A study of Drosophila melanogaster with 48 samples.

How the data were processed

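CUT&RUN was carried out on S2 cells and on larval brains, and the peak lists analysed here come from 4 brain samples with an antibody against Zld, in 2 conditions of 2 replicates each, with 1 list per condition. Groups were taken from the sample titles. The genotype label is the same for both conditions and names the UAS-HA-Zld transgene in each, so the assignment of the lists to conditions rests on the titles alone. Per the submitters' processing notes, Bowtie2, MACS2 and deepTools 3.5.1 were used with the genome build dm6. Whether reads or calls of the replicates were pooled, which control MACS2 was given and which filters followed are not given in the sources used here.

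The deposited lists are in the narrowPeak layout. Each gives, as the authors' caller wrote them, an integer score, the fold enrichment at the summit (a ratio of pileup to local background, each with 1 added), and the −log10 of the p-value and of the q-value. The position of the summit within the peak stands beside them. A peak with several summits has several rows. A peak was counted here as 1 distinct interval, and its location was taken from the summit with the highest −log10 q. The lists held 13826 summits in brat and 16252 in UAS-HA-Zld, and all peaks lay on the 6 arms 2L, 2R, 3L, 3R, 4 and X. The smallest −log10 q was 1.31 and 1.30. Median peak width was 574 bp (quartiles 387 and 887) in brat and 549 bp (372 and 850) in UAS-HA-Zld.

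The fold enrichment and the −log10 p together fix the pileup and the background under the Poisson test that MACS2 uses. Solving for both gave a whole-number pileup within a relative tolerance of 0.0001 for 100% of summits in each list. The floor of the background, taken as genome-wide coverage, was 22.6 fragments in brat and 28.8 in UAS-HA-Zld, 1.28 times higher in the latter. Above the floor, at 189 summits on the same base in both lists, the ratio of the backgrounds had a median of 1.45 and a central 95% of 1.41 to 1.56. The backgrounds were thus nearly proportional, so that both lists may have been scored against 1 control track. The floors and this ratio were used only as estimates of relative depth, and the position of a high local background was not assigned to a condition. The solver was tested on simulated data, where it recovered 100% of 4597 pileups and fitted 0% of half-integer ones.

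Peaks were matched when they shared at least 1 bp. Shares carry Wilson 95% intervals, which cover counting error only. Matched shares were compared with 1000 placements of the other list at random within each arm with widths kept, and locations with 1000 random placements of the class itself. In a simulated list, all peaks left in place were matched and 3.66% of randomly moved ones. No test between conditions was run because there was 1 list per condition.

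Genes came from a table of the RefSeq annotation of the same assembly, with 17684 genes on the 6 arms, 13922 of them protein-coding. It gives the start and end of each gene without the strand. The plan had been to use transcription start sites. Both ends of a gene were used in their place, 500 bp for locations and 2 kb for gene lists. Exons, introns and UTRs could not be assigned for the same reason. A planned count of Zld motifs under the peaks was not run because it needs a genome sequence, which was not used here.

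The 14 gene lists were written before the data were examined, as were the planned tests and alternatives. They cover type II neuroblast and stem cell identity, intermediate neural progenitors, temporal patterning, the Notch pathway, the cell cycle, neurons, glia, early embryo Zld targets, Hox genes, muscle, germline, fat body, trachea and sequences the transgenes may carry. All their genes were found in the gene table, 3 of them under another symbol. Some genes are in more than 1 list. Random lists were drawn 10000 times from protein-coding genes in the same 10 bins of gene length. Tested on simulated random lists, 2% lay above the central 95% of draws.

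Named peaks are, for each class, the 10 with the highest −log10 q whose summit lay in a protein-coding gene or within 5 kb of an end of one, called by the gene with the nearest end. To these were added the 5 genes with the most UAS-HA-Zld-only peaks, up to 4 members of each gene list with the strongest peak, and any member with a peak in 1 list only. Strength within a gene list was read from the brat list, a choice made when the text was written.

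Alternatives were stricter thresholds (−log10 q of at least 5 or 10), equal list lengths, stricter matching, other distances to gene ends, assignment of each summit to the nearest gene and random lists not matched on length. Others were added after the data were seen. These were summits as the unit, scaling to equal coverage, protein-coding gene ends and leaving out arm 4. Further ones left out the list of transgene sequences, or unmatched peaks beside absent peak numbers in the other list. Without the list of transgene sequences, zld and wor still counted, being also in the type II neuroblast list. The computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.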

Results

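The series holds 48 CUT&RUN samples from Drosophila melanogaster, 42 from S2 cells, a line derived from embryos, and 6 from brains of third-instar larvae. CUT&RUN releases the DNA around an antibody-bound protein with a tethered nuclease, so that sequenced fragments pile up where the protein was bound. The values below come from the brain experiment with an antibody against Zelda (Zld), the pioneer transcription factor that opens chromatin at the first genes transcribed in the embryo. Its 4 anti-Zld samples form 2 conditions of 2 replicates each. The first condition, called brat here, is brains with mutant alleles of brat, a translational repressor whose loss makes type II neuroblasts, the neural stem cells that divide through intermediate progenitors, accumulate. The second, called UAS-HA-Zld here, is named in its titles for an HA-tagged Zld under Gal4 control, and its genotype label gives a Gal4 line active in neuroblasts. The genotype label is the same for the first condition, so whether that one lacks the transgene rests on the titles. The titles name brat for the first condition only, so whether brat alleles, and with them cell types, also differ was not established here. Larvae were kept at 18°C and moved to 33°C for 24 h, and each reaction used 50 brains. One peak list per condition was analysed, with none per replicate, so no difference between the conditions could be set against replicate spread. The S2 samples and the 2 brain samples with control IgG were not analysed here. Both IgG brain samples are titled brat, and none is titled UAS-HA-Zld. Both lists held whole fragment pileups, with a median at the summits of 147 fragments in brat and 208 in UAS-HA-Zld, and a genome-wide background of 22.6 and 28.8 fragments.

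Going by the titles, the first comparison asks how far the places where Zld is found differ with its forced expression. In brat brains the authors' list held 7644 peaks covering 5.52 Mb, and in UAS-HA-Zld brains 9065 peaks covering 6.30 Mb, 1.19 times as many. Of the brat peaks, 5968 shared at least 1 bp with a UAS-HA-Zld peak, which is 78.1% (Wilson 95% interval 77.1 to 79.0). Of the UAS-HA-Zld peaks, 6085 shared bases with a brat peak, which is 67.1% (66.2 to 68.1). Placing the other list at random within each chromosome arm 1000 times matched a median of 9.45% of brat peaks (central 95% of draws 8.77 to 10.1) and 8.01% of UAS-HA-Zld peaks (7.42 to 8.57). That left 1676 peaks found only in the brat list and 2980 found only in the UAS-HA-Zld list. With only as many top UAS-HA-Zld peaks as the brat list holds, the shares were 70.8% and 71.7%. The intervals cover counting error only.

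Most of the strongest sites were common to both conditions. The highest-ranking shared peaks lay at CG34460 (2R, 16830060 to 16831864, outside protein-coding genes, fold enrichment 86.4 in the brat list), at the corepressor gene Smr (X, 12741977 to 12742841, fold 70.4), at the end of the growth regulator chrb (3L, 11487290 to 11488039, fold 56.3) and inside vri, a transcription factor of the circadian clock (2L, 5305017 to 5307128, fold 46.6). They were followed by peaks at Amun, kek5, the sodium pump subunit gene nrv2, the translation initiation factor gene eIF4A, Cph and the profilin gene chic, with folds of 30.0 to 58.8. All fold enrichments are the authors' values for single peaks and rank peaks only within their own list.

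Matching rose with peak strength in both lists. From the weakest to the strongest quintile by −log10 q, 55.7%, 68.0%, 79.8%, 90.3% and 96.5% of brat peaks were matched, against 44.3%, 58.1%, 67.4%, 76.5% and 89.3% of UAS-HA-Zld peaks. The strongest quintile held 53 unmatched peaks of 1529 in the brat list and 194 of 1813 in the UAS-HA-Zld list. Median fold enrichment was 2.91 for brat-only and 4.46 for shared peaks of the brat list, and 2.94 and 4.32 for those of the UAS-HA-Zld list. Unmatched peaks were also narrower, with median widths of 388 against 640.5 bp and 435 against 622 bp.

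**Figure D1:**
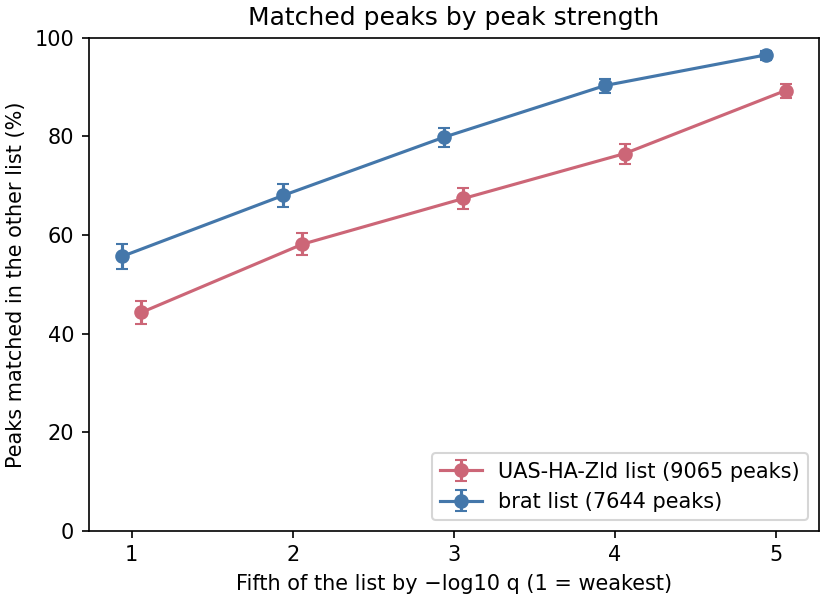
Percentage of peaks that share at least 1 bp with a peak of the other list (y axis) by quintile of −log10 q within each list (x axis, 1 weakest), with points for the percentage and bars for Wilson 95% intervals. The percentage rose from 55.7 to 96.5 in the brat list and from 44.3 to 89.3 in the UAS-HA-Zld list.

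Peaks found only with UAS-HA-Zld included strong ones at genes of early development. The highest-ranking lay 445 bp from nullo, a gene of embryonic cellularisation (X, 7048470 to 7050213, fold 46.5, summit inside CG12541), and was the peak with the highest fold of the whole list. Next came a peak inside run, a pair-rule transcription factor gene (X, 20691264 to 20692260, fold 23.5), one inside SKIP (3R, 22151603 to 22154099, fold 21.5), and one 3.16 kb from Tom, a Bearded-family gene (3L, 14965689 to 14966789, fold 35.3). The Hox gene Antp held one inside its gene body (3R, 6978175 to 6978796, fold 18.8), for which the nearest end of a protein-coding gene belonged to CG46458. Others lay at CG43131 (fold 25.4), inside Ten-m (fold 21.6), inside jing with CG15233 as the gene with the nearest end (fold 15.9), near the ecdysone synthesis gene phtm (fold 24.0) and near upd1, a ligand of the JAK/STAT pathway (fold 20.04). The genes with the most such peaks were bru3 with 25, jing with 22, olf413 with 20, and SKIP and heph with 16 each, all long genes of 112 to 281 kb. Of these 5, bru3, olf413 and SKIP had 0 brat-only peaks, jing had 1 and heph had 4.

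The highest-ranking peak found only in the brat list was inside pk, 1.78 kb from CG30384 (2R, 7186809 to 7187606, fold 75.2). It was followed by a peak at Mitf, a regulator of lysosomal genes (4, 1198727 to 1199654, fold 43.1), and by peaks at the acetyltransferase gene enok (fold 24.8), eIF2beta (18.9), Mzt1 (18.3, inside Svil), Cnot4 (27.0), MAN1 (14.8), Alg-2 (18.0), mthl14 (14.3) and the MAP kinase gene rl (20.6). The peaks in each list carry running numbers, and 19.5% of the numbers are absent from each list, 1846 in brat and 2191 in UAS-HA-Zld, so some called peaks are not among those analysed. For all 10 of these brat-only peaks at least 1 UAS-HA-Zld number was absent between the neighbouring peaks, against 5 of the 10 UAS-HA-Zld-only peaks named above. Those at nullo, Tom, Ten-m, phtm and upd1 had none.

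The second comparison asks where shared and unmatched sites lie relative to genes. UAS-HA-Zld-only sites lay far from gene ends more often than the other classes. The strongest summit lay within 500 bp of either end of an annotated gene for 43.1% of shared peaks (2570 of 5968, interval 41.8 to 44.3), 46.3% of brat-only peaks (776 of 1676, 43.9 to 48.7) and 22.2% of UAS-HA-Zld-only peaks (663 of 2980, 20.8 to 23.8). Random placement gave 18.0% for the last class (central 95% of draws 16.7 to 19.3). Elsewhere inside genes lay 42.0%, 39.3% and 49.6% of the classes in that order, and outside genes 15.0%, 14.4% and 28.2%. The median distance from the summit to the nearest gene end was 805.5 bp, 627.5 bp and 2653.5 bp. Within each quintile of strength of the UAS-HA-Zld list, shared peaks exceeded UAS-HA-Zld-only peaks near gene ends by 18.9 to 26.7 percentage points. Gene strand was not used here, so starts and ends of genes are counted together.

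**Figure D2:**
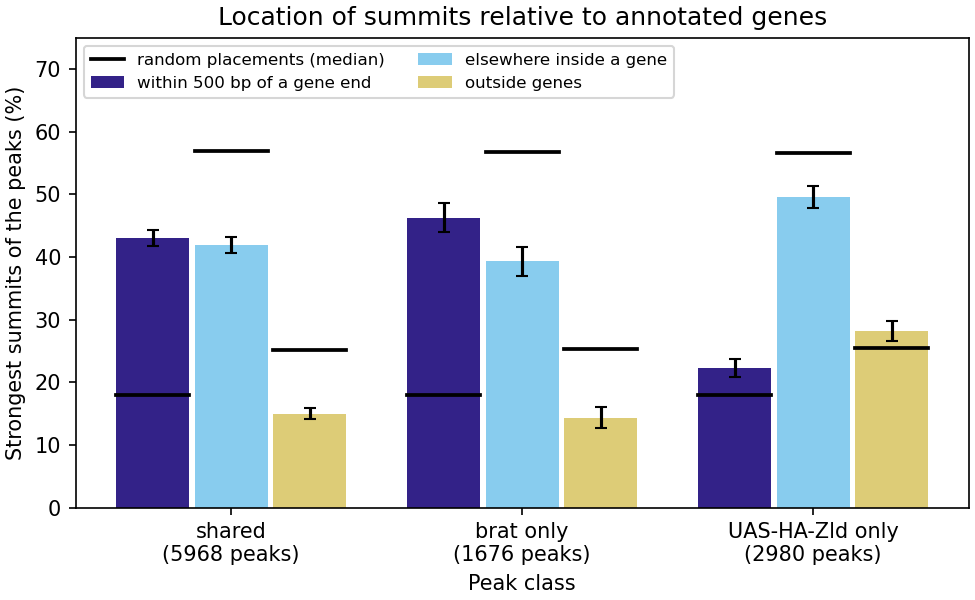
Percentage of strongest summits (y axis) within 500 bp of a gene end, elsewhere inside a gene and outside genes, for shared, brat-only and UAS-HA-Zld-only peaks (x axis), with Wilson 95% intervals as error bars and the median of 1000 random placements as black lines. The bar near gene ends is 22.2% for UAS-HA-Zld-only peaks, against 43.1% for shared and 46.3% for brat-only peaks.

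The third comparison asks which groups of genes gained or lost sites. A summit in a gene or within 2 kb of either end was found for 6049 of 13922 protein-coding genes in the brat list (43.4%) and 5995 in the UAS-HA-Zld list (43.1%). There were 2176 genes with a UAS-HA-Zld-only peak and 2100 with a brat-only peak. For each of 14 gene lists the number of members with a peak was set against 10000 random lists of protein-coding genes of matched length, a description of these 2 peak lists and no test of the conditions. Of the 155 distinct genes of these lists, 110 had a peak in brat and 121 in UAS-HA-Zld, 73 had a UAS-HA-Zld-only peak and 35 a brat-only peak. Members named first in each list are those with the highest −log10 q in the brat list, and those with peaks in 1 list only are all named.

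All 15 genes of the type II neuroblast and stem cell list had a peak in both conditions, where random lists gave 6 to 12. The strongest brat peaks lay at grh (fold 33.8), brat itself (36.6), the receptor gene N (35.1) and zld (25.9). UAS-HA-Zld-only peaks lay at 11 of the 15 (random 1 to 8) and brat-only peaks at 5 (random 1 to 7). The 11 include zld, with 2 such peaks, and wor, with 1, which are also in the list of sequences the transgenes may carry. Chosen after its values were seen for its number of such peaks, Sp1, a zinc-finger factor gene, went from 3 peaks to 13, and 10 of these were UAS-HA-Zld-only. Also chosen that way, tll went from 2 peaks to 5, klu from 2 to 5 and pnt from 11 to 16. In the window around Sp1 and its neighbour btd, 21 of 37 UAS-HA-Zld peaks were unmatched, against 1 of 16 brat peaks.

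**Figure D3:**
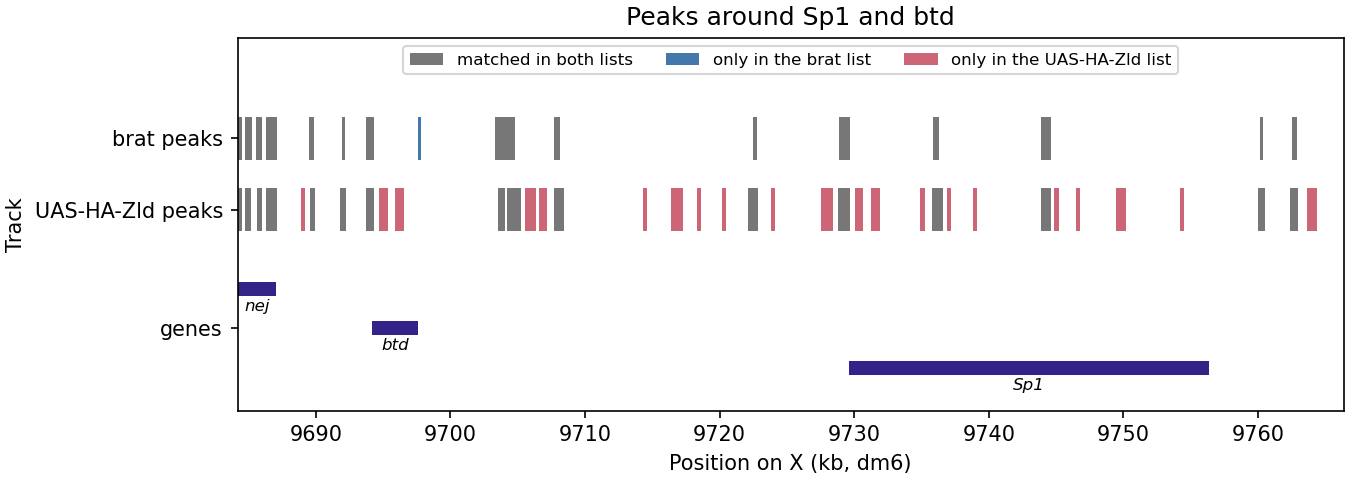
Map of the X chromosome from 9684186 to 9766369 (dm6, x axis in kb). Boxes to scale are the peaks of both lists and the protein-coding genes. Grey peaks are matched and coloured ones are in 1 list only. Of 37 UAS-HA-Zld peaks 21 are unmatched, and of 16 brat peaks 1 is.

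Among 10 genes of intermediate neural progenitors, 9 had a brat peak and all 10 a UAS-HA-Zld peak. The strongest were at D (fold 22.6), osa (18.3), ham (10.2) and dac (13.5), and Fer1 had 3 peaks with UAS-HA-Zld and none in brat. Of the 10, 7 had a UAS-HA-Zld-only peak (random 1 to 6) and 2 a brat-only peak. This count fell inside the central 95% of random lists under 4 alternatives, with percentiles of 86.5 to 97.4. All 13 temporal patterning genes, which set neuroblast age, had a peak in both lists, the strongest at Eip93F (fold 31.8), svp (8.78), br (28.4) and nub (21.3). UAS-HA-Zld-only peaks lay at 11 of them (random 1 to 8), among them Imp with 7, whose strongest had a fold of 17.3, and chinmo with 5, both picked after their values were seen. Brat-only peaks lay at 5 of the 13 temporal genes (random 1 to 7). Counting only summits within 1 kb of a gene end brought the temporal count to the 15.9th percentile.

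Notch pathway genes had a peak in 14 of 15 cases in brat and in all 15 with UAS-HA-Zld, and 9 had a UAS-HA-Zld-only peak (random 1 to 7) against 4 with a brat-only peak. The strongest besides N were at E(spl)m8-HLH (fold 25.1), numb (19.0) and Ser (7.91), and E(spl)m5-HLH had a peak only with UAS-HA-Zld (fold 2.66). The E(spl) genes are neighbours, so 1 peak can count for several of them. Of 12 cell cycle genes 11 had a peak in each list, led by CycA (fold 17.6), E2f1 (11.9), stg (10.7) and Cdk1 (17.6). PCNA, the replication clamp gene, had a peak only with UAS-HA-Zld (fold 5.56), and aurA only in brat (3.10). The 5 cell cycle genes with a UAS-HA-Zld-only peak lay within the random range of 0 to 5, and 3 had a brat-only peak.

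Early embryonic Zld targets showed the largest gap between the unmatched classes of the 14 lists. Of 22 genes, 15 had a brat peak and 20 a UAS-HA-Zld peak. UAS-HA-Zld-only peaks lay at 12 (random 1 to 7) and a brat-only peak at 1, sog. The 5 genes with a peak only with UAS-HA-Zld were nullo (fold 46.5), sisA (11.2), an X-linked signal of sex determination, the pair-rule genes ftz (7.43) and prd (4.91), and bnk (4.20). The strongest brat peaks lay at brk (20.8), Kr (15.6), rho (12.9) and tll (6.73), all also found with UAS-HA-Zld, and zen and slam had no peak in either list. Of the 8 Hox genes, 7 had a brat peak and all 8 a UAS-HA-Zld peak, pb being the one gained, with 2 peaks (fold 8.48 at the stronger). UAS-HA-Zld-only peaks lay at 5 Hox genes (random 0 to 6) and brat-only peaks at 3. Abd-B (fold 15.0) and Antp (4.53) held the strongest brat peaks, and Ubx had 3 peaks in brat and 1 with UAS-HA-Zld.

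Of 14 neuronal genes 12 had a peak in each list, led by pros (fold 19.8), elav (9.53), nSyb (8.41) and nerfin-1 (6.44), and 4 had a UAS-HA-Zld-only peak (random 1 to 8) against 6 with a brat-only peak. ChAT and VAChT overlap, so the same 2 brat-only peaks count for both genes. The 9 UAS-HA-Zld-only peaks at pros, a gene that acts as progenitors leave the stem cell state, were singled out after their values were seen. Of 11 glial genes, 7 had a peak in brat and 8 with UAS-HA-Zld, led by nrv2 (58.8), Eaat1 (4.82), gcm2 (5.21) and loco (4.17). The glial gene repo had a peak only in brat (fold 2.19), and moody (1.59) and Gli (2.97) only with UAS-HA-Zld. Of the glial genes, 6 had a UAS-HA-Zld-only peak (random 0 to 5) and 2 a brat-only peak. The glial count fell inside the random range under 3 alternatives, with percentiles of 80.9 to 93.1. In 2 of them, −log10 q of at least 10 and equal list lengths, the order turned, with 3 glial genes having a UAS-HA-Zld-only peak and 5 a brat-only peak.

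Of 10 muscle genes only Mef2 (fold 13.4) had a peak, in both lists, where random lists of the same length gave 4 to 9 genes in brat and 3 to 9 with UAS-HA-Zld, and 0 had an unmatched peak. Of 8 germline genes 3 had a brat peak, at osk (7.60), nanos (5.76) and vas (7.75), and 4 a UAS-HA-Zld peak, the added one at tud (2.34), with UAS-HA-Zld-only peaks at 1 and brat-only peaks at 2. Of 8 fat body genes, Lpin (6.25) and apolpp (7.76) had a peak in each list, and Lpin also had a UAS-HA-Zld-only peak. Of 6 tracheal genes 4 had a peak in each list: trh (4.91) and serp (1.95) in both, dysf (2.43) and verm (2.12) only in brat, and the receptor gene btl (4.01) and its ligand gene bnl (6.01) only with UAS-HA-Zld. Brat-only peaks lay at 3 of them and UAS-HA-Zld-only peaks at 2, which became 0 and 2 with −log10 q of at least 10. All these counts lay within the random range except for the number of muscle genes with any peak. The 0 muscle genes with an unmatched peak lay within it (random 0 to 5 for either class). Of 9 genes whose sequence the transgenes may carry, zld (25.9), alphaTub84B (13.1) and wor (5.33) had peaks in both lists, w had 3 peaks only with UAS-HA-Zld (strongest fold 2.39), and the 5 Hsp70 genes had none. UAS-HA-Zld-only peaks lay at 3 of the 9 (random 0 to 4) and brat-only peaks at 0.

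**Figure D4:**
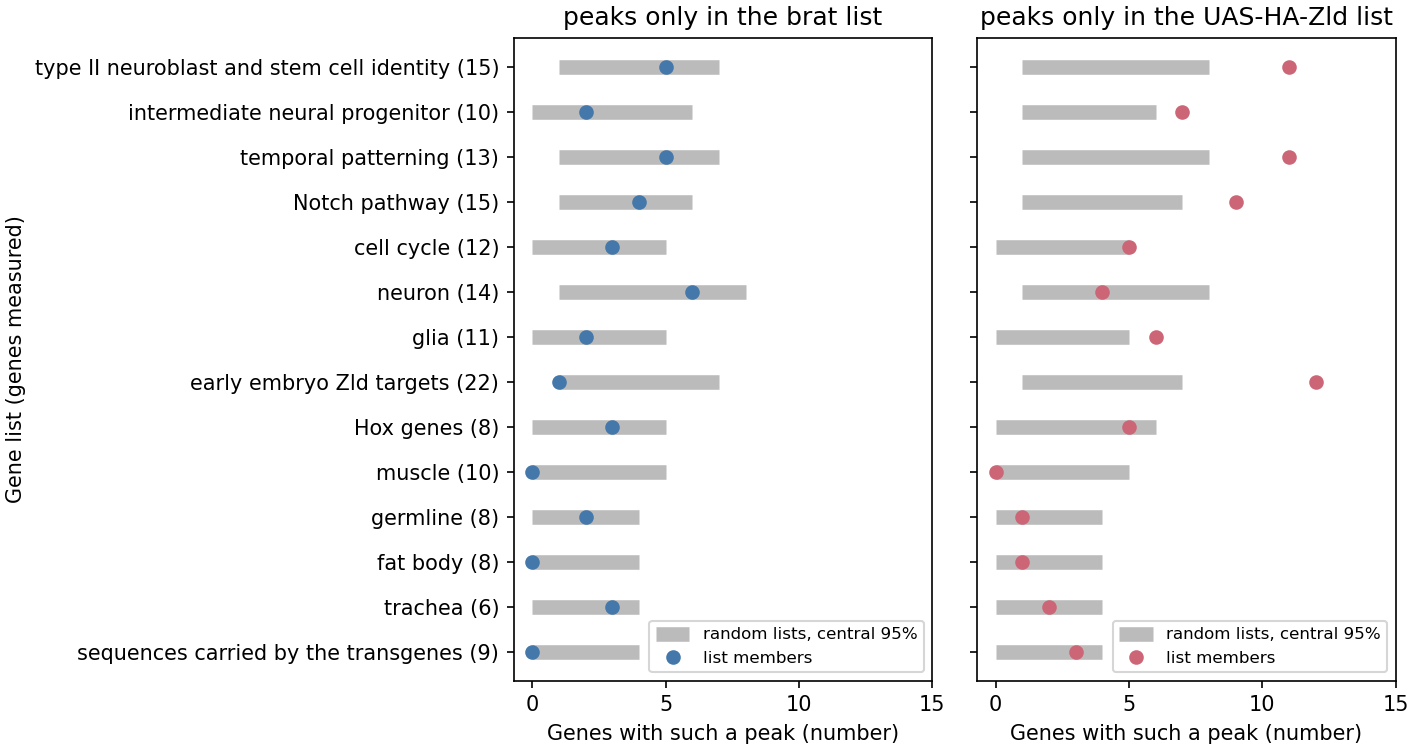
Number of genes of each list (x axis) with a peak only in the brat list (left) or only in the UAS-HA-Zld list (right), by gene list with the number of genes measured (y axis), with points for the list and grey bars for the central 95% of 10000 random lists of matched gene length. Early embryo targets reached 12 genes with a UAS-HA-Zld-only peak against a random range of 1 to 7. Muscle genes had 0, within their random range of 0 to 5.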

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

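All tests in this part were chosen after the result was seen. The gene w, whose sequence marks many fly transgenes, was counted above in the list of transgene sequences, and 3 peaks covered it in the UAS-HA-Zld list and none in the brat list (X, gene from 2790599 to 2796466). They drew attention through their local background, a value outside the 3 comparisons of the report, which reached 12.1 times the genome-wide floor at the peak from 2791838 to 2793096, where the median over the peaks of that list was 2.18. Extra copies of w on transgenes stay open as an explanation: the lowest background percentile of the 3 peaks among all peaks of the list, 98.3, is the value that drew attention and so cannot test it. The control that MACS2 took the background from is not given in the sources used here, so the background need not come from UAS-HA-Zld animals. Both brain samples with control IgG are titled brat. Binding of Zld there stays open too, because their highest fold enrichment, at the 21.6th percentile of the list, does not forbid weak binding. It is also open whether brat had peaks here, since 5 brat peak numbers are absent from the stretch of 147 kb around w that holds no brat peak.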

How the results depend on the processing

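No paired analysis was possible because each condition has 1 peak list and no list per replicate, and for the same reason no replicate could be left out. The settings meant for the Zld motif were not run without a genome sequence. Over all settings, 78 values of the main results stayed within their interval or within 1.5 times their count and 25 did not. Of the counts for single gene lists 334 stayed and 58 moved, of their percentiles 92 kept their side of the central 95% and 20 did not. The values that stayed include those of 1 planned setting, all sequences in the files. It repeated the main run, because all peaks lay on the 6 arms, and so could not move any value. The named shared peaks kept a match under each setting run for them, while stricter settings could hardly have given the unmatched ones a match. The order of brat-only and UAS-HA-Zld-only gene counts turned for 2 lists: glia, from 2 and 6 to 5 and 3, with −log10 q of at least 10 and with equal list lengths, and trachea, from 3 and 2 to 0 and 2, with −log10 q of at least 10. With −log10 q of at least 10, the matched share of UAS-HA-Zld peaks was 65.8% and brat-only summits near gene ends 49.2%. With equal list lengths, matched shares were 70.8% in brat and 71.7% in UAS-HA-Zld, so that brat was no longer above, with overlapping intervals, as fewer UAS-HA-Zld peaks could be matched, and UAS-HA-Zld-only summits near gene ends were 20.1%. With summits within 200 bp as the match, shares were 75.3% and 64.6%. Near gene ends, shared, brat-only and UAS-HA-Zld-only peaks had 32.3%, 36.0% and 14.2% within 250 bp, and 53.1%, 55.5% and 31.9% within 1000 bp. Counting only summits within 1 kb of a gene end left 13 list genes with a brat-only and 32 with a UAS-HA-Zld-only peak. Among alternatives chosen after the data were seen, leaving out unmatched peaks beside absent numbers gave matched shares of 90.2% and 80.9%. These shares could only rise, because all matched peaks were kept. With that setting, 19.3% of UAS-HA-Zld-only summits lay near gene ends and 20 list genes had a brat-only peak, a count that could only fall. Using all summits gave 20.8% for UAS-HA-Zld-only peaks, and protein-coding gene ends gave 37.9%, 42.3% and 17.9%. Counting summits gave 13826 and 16252 in place of peaks. The cause of these shifts was not tested beyond what each setting changes by construction. For UAS-HA-Zld-only peaks, the cell cycle list rose above the central 95% of random lists under 4 alternatives (98.0 to 99.7) and the Hox list under 2 (99.4 and 99.8). The muscle list, with 0 genes in a random range of 0 to 5, moved from the 2.14th percentile to between the 2.63rd and 19.4th under 6. With −log10 q of at least 10 its count stayed at 0, so only the percentile shifted there.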

Other observations

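The fourth chromosome went the other way from the rest of the genome, a comparison chosen after the data were seen. On it the brat list held 137 peaks and the UAS-HA-Zld list 88. Only 71 of the brat peaks were matched, 51.8% (Wilson 95% interval 43.5 to 60.0), against 75.9% to 81.2% on the other arms, while 77 of the UAS-HA-Zld peaks were, 87.5% (79.0 to 92.9), against 63.9% to 70.5%. Genes on it with fewer peaks under UAS-HA-Zld included the eye selector gene ey (3 in brat, 1 with UAS-HA-Zld) and the neuronal factor gene onecut (3 and 2). Of the 3 brat peaks, 1 at ey and 2 at onecut were unmatched. Cadps, a gene of vesicle release, had 6 brat-only peaks and 0 in the other list. Of the 66 brat-only peaks on this arm, 44 had an absent UAS-HA-Zld number around them (66.7%), close to the 61.5% of all brat-only peaks. On other arms brat-only peaks were most frequent at d4 and mam, with 7 each, and at Tet with 6. Unmatched sites lay nearer to sites of the other list than randomly placed ones. The median distance to its nearest summit was 4.18 kb for brat-only peaks (random 9.59 kb) and 3.44 kb for UAS-HA-Zld-only peaks (random 10.1 kb). The 200 random placements covered the whole arm and did not keep any clustering of peaks, so ordinary clustering was not separated from nearness to the other list.

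In the paragraphs that follow, all tests were chosen after the data were seen. For prior binding at gene lists and for location without peaks beside absent numbers, the outcome each explanation requires was written before the value was seen. UAS-HA-Zld-only peaks could come from deeper UAS-HA-Zld coverage, as estimated from the backgrounds, but 98.5% of them (2935 of 2980) stayed past the brat threshold after scaling down by 0.784, as did 8997 of all 9065, and 97.9% did at 0.688, from the background at summits on the same base. A factor of 0.0475 would be needed to bring 50% of them below it, so a depth difference of the estimated size is argued against as the whole cause. The scaling left out sampling noise and any difference in enrichment between the libraries. Peaks called in brat and then removed cannot account for the 1437 with no absent brat number around them, while for the other 1543 this cannot be told apart from a gain, as the positions of absent peaks are not in the list; if each absent brat peak matched only 1 of them, at most 949 could be accounted for. Gain at genes that already had shared peaks was tested for 3 lists. Random lists were matched on length and number of shared peaks, with 4 or more taken as 1 class. Early embryo targets (12 genes, random 1 to 7), type II neuroblast genes (11, random 3 to 10) and temporal genes (11, random 4 to 10) had percentiles of 99.995, 99.55 and 98.62. Early embryo targets had at most 3 shared peaks each, so for them the value argues against this explanation. Genes of the other 2 lists had up to 13 (grh) and 19 (EcR), which the matching did not equalise, so for them it stays open. The type II neuroblast count also includes zld and wor, whose sequence the transgenes may carry. The test was run with summits in a gene or within 2 kb of an end. The temporal excess itself is absent, at the 15.9th percentile of lists matched on length alone, when only summits within 1 kb of a gene end count. Added binding from forced Zld expression is a hypothesis that stays open without replicate lists, and the shared genotype label leaves the assignment of conditions to the titles.

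UAS-HA-Zld-only summits were near gene ends less often than shared ones (22.2% against 43.1%), though more often than random placement (18.0%). The excess over random placement was absent in the strongest quintiles (15.7% and 16.0%). The gap from shared peaks could follow if weaker peaks lie farther from genes. Within quintiles of strength the smallest difference from shared peaks was 18.9 percentage points, which argues against this. In the UAS-HA-Zld list the share was also higher in the weakest than in the strongest quintile, for unmatched (26.5% and 16.0%) and shared peaks (45.5% and 36.6%). In the brat list it was lower, for unmatched (38.6% and 52.8%) and shared peaks (34.8% and 48.0%). Peaks that are unmatched only because their match was removed from the other list might also shift the classes apart. With unmatched peaks beside absent numbers of the other list left out, brat-only peaks still exceeded UAS-HA-Zld-only peaks near gene ends by 25.0 percentage points. Peaks removed from a class's own list were not covered, because their positions are not known, so their effect on the shares stays open. A different kind of site reached at higher Zld levels is a hypothesis, untested here without a genome sequence to search for its motif.

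Strong brat-only peaks had an absent UAS-HA-Zld number around them more often than weak ones, 92.5% (interval 82.1 to 97.0) in the strongest quintile against 53.2% (49.5 to 57.0) in the weakest, where random positions gave 46.8%. For UAS-HA-Zld-only peaks the values were 46.4% (39.5 to 53.4) and 52.3% (49.2 to 55.3), with 39.7% at random positions.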
